A study of Homo sapiens with 2 samples.

How the data were processed

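Total RNA of U87 cells was measured on 2 Agilent one-colour arrays labelled with Cy3, 1 from cells with a negative control mimic and 1 from cells with miR-145-5p and miR-31-5p mimics. Per the file headers, the scanner files hold intensity values made with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. The processed signal is a background-subtracted and detrended intensity, with values near background replaced by a surrogate above 0. The deposited value table also holds intensity, on a linear scale, and its 2 columns hold the same sorted values to within 0.0943, as quantile normalization leaves them. The median of each column was 16.7. Its scale and normalization are known from comparison with the scanner files, since its steps are not stated. Its per-sample columns were all used as an alternative.

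Each array held 62976 spots, of which 60901 were not controls, for 58201 probes of 60 bases. A set of 300 probes was printed as 10 spots each. Spots well above background numbered 25668 on the control array and 27201 on the mimics array. The 75th percentile of the processed signal was 157.0 and 158.7. No spot was saturated. An outlier mark was set on 4113 control and 1807 mimics spots, and 109 and 103 of these concerned the spot itself and not its background. Among 308 negative control spots, 11 and 8 were well above background. The software's detection limit statistic was 1.73 and 2.63. The median coefficient of variation over replicate spots was 3.98% and 4.08%. The 7 spike-in transcripts above background on both arrays differed by -0.17 to -0.01, with a median of -0.07.

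The processed signal was put on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. Control spots and spots with any of 4 outlier marks on that array were left out, and the spots of a probe were averaged. A probe was measured where it was well above background on both arrays, and a gene's difference was the median over its measured probes of mimics minus control. Probes were named with a human gene table of assembly GRCh38.p14, used for names alone. The accession named 31104 probes, the symbol 3366 and an older symbol 496, while 23235 had no name there. The 34966 named probes covered 23556 genes, of which 12601 were measured, 9569 by 1 probe and 3032 by more. In 21 of the latter, probes differed by over 0.5 in both directions. Probe positions are those the scanner files give on hg19. They do not say which exon or untranslated region a probe lies in.

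With 1 array per group no test, p-value or error between replicates exists. Genes were called by a size of 2-fold alone. The technical spread was taken from probes with replicate spots. The SD of the difference between the arrays was 0.54 for signals of 4 to 16, 0.36 up to 64, 0.18 up to 256, 0.10 up to 1024, 0.06 up to 4096 and 0.05 beyond. It holds no variation between cultures. At replicate spots above background on both arrays, the difference between the arrays had an SD of 0.09 around its mean for the probe. It was 0.08 in clean and 0.12 in speckled cells of the array. A shift between the arrays that all spots of a probe share is in none of these SDs.

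The following choices were made before the data were examined: the settings above, the other settings to try, the gene lists and the rule for named genes. The 29 lists were reported targets of miR-145-5p and of miR-31-5p, mitosis, DNA replication, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, extracellular matrix, integrins, proteases of invasion, actin cytoskeleton and contractile genes, glioma stem cell and neural markers, mesenchymal glioma genes, hypoxia targets, unfolded protein and integrated stress response, sterol and fatty acid synthesis, immediate early and MAP kinase feedback genes, TGF-beta and YAP targets, growth factor receptor, PI3K and RAS signalling, apoptosis, microRNA machinery, ribosomal proteins, replication-dependent histones, housekeeping genes, and markers of neurons, oligodendrocytes, microglia and macrophages, endothelium and epithelium. They were written from general knowledge. Each list's median was placed as a percentile among 10000 random lists of the same size drawn from 20 bins of mean signal. A percentile outside the central 95% describes these 2 arrays and is no test of the treatment. Named genes were the 12 largest differences each way among genes of at least median brightness whose measured probes were all 2-fold away in the same direction, the 4 largest absolute differences in each list (8 for each target list), the 4 largest bounds each way among genes above background on 1 array, and the host transcripts. The text does not print every gene this rule takes. For a gene above background on 1 array alone, the fold is a lower bound against the higher of its own value and the lowest value of any probe above background on the dim array.

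The settings planned as alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), quantile normalization, scaling by the median of measured probes, no scaling, the deposited value table, no filter on dim probes, a processed signal of at least 100, keeping spots with outlier marks, the brightest probe per gene, size thresholds of 1.5-fold and 3-fold, and a floor at the 5th percentile. The division of the array into clean and speckled cells, the use of the 2 marks on the spot itself alone, scaling by the spike-ins, and a search of probe sequences for seed matches were chosen after seeing the data. Clean cells were first scaled on their own spots and afterwards with the whole array, and both versions are given. Seed sites in 3′ untranslated regions had been planned, with their own named genes and alternatives, but no sequence of these regions was available and they were not searched. In their place, a gene was counted as holding a seed match where a measured probe held either of 2 words of 7 bases that pair with the seed. The search was first explored on single probes with a filter on signal, before it was set up per gene. Words held by at least 20 genes were ranked by median difference, the planned statistic, and by standardised mean. The plan for untranslated regions had set this cut at 100 genes. The miR-31-5p words TCTTGCC and CTTGCCA were held by 63 and 79 genes, and would not have been ranked under that cut.

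The steps were tested on data simulated from the control array's spots and detection marks, with noise wider than measured for signals of 16 to 64. Of 50 genes simulated at 1.5-fold, 0 were called, against 49 at 2.5-fold and 50 at each of 4-fold and 8-fold. Of 13006 unchanged genes, 46 (0.354%) were called. A list shifted by -0.3 was recovered at -0.31, and 2% of 200 unchanged lists lay outside the central 95%. A word whose genes were lowered by 0.5 ranked 1 of 12371. The holders of the miR-31-5p words differed from other genes by only -0.11 and -0.14, so that rank does not tell whether such shifts would be found. All 30 of 30 genes made dark on 1 array were found, but they were set to meet the definition itself, so this checks the steps alone. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.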

Results

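The data were 2 one-colour gene expression arrays of U87 cells, a human glioblastoma line. One array carried RNA from U87 cells transfected with a negative control mimic, and the other RNA from U87 cells co-transfected with mimics of miR-145-5p and miR-31-5p. A mimic is a synthetic double-stranded RNA that enters the silencing machinery as the mature microRNA would. Each group had 1 array, both arrays lay on 1 slide, and every difference given here is therefore without a replicate check. Of the 60901 non-control spots, 42.1% were well above background on the control array and 44.7% on the mimics array. A gene's value was its processed signal on the log2 scale relative to the array's 75th percentile, and 12601 named genes were measured on both arrays. Differences are given as mimics minus control. The number of arrays limits the precision, and the only error available was the technical spread between spots.

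The comparison addressed which transcripts differed between U87 cells that received both microRNA mimics and U87 cells that received the control mimic. With the mimics, 231 genes were at least 2-fold lower and 103 at least 2-fold higher, or 103 and 38 with normexp background correction. STK40, a kinase-like protein and reported miR-31-5p target, was 5.42-fold lower with the mimics. The reported targets of miR-31-5p had a median difference of -0.29 and those of miR-145-5p one of -0.13. With the arrays scaled by the spike-ins, these medians were -0.22 and -0.06. All 19 measured DNA replication genes were lower on the mimics array, with a median of -0.36. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, was 3.02-fold higher with the mimics.

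Part of the 2-fold counts went with position on the array. The array was divided into 336 cells of 16 rows by 12 columns, and a cell was called speckled where at least 2% of the spots with no significant signal on one array were well above background on the other. In the 188 clean cells, 67 of 7997 genes (0.838%) were at least 2-fold lower and 17 (0.213%) at least 2-fold higher. In the speckled cells, 222 of 6496 genes (3.42%) were at least 2-fold lower and 105 (1.62%) at least 2-fold higher. Genes with probes in both kinds of cell entered both counts. In data simulated over the whole array, 0.354% of genes without a difference reached 2-fold, both directions together. The noise simulated for signals of 16 to 64 was wider than the measured SD of 0.36 (0.33 in clean cells). The simulated share is thus no chance level for either kind of cell. Because calls went with position, the kind of cell is given for the genes with the largest differences. List members with no probe in a clean cell are named as such.

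**Figure D1:**
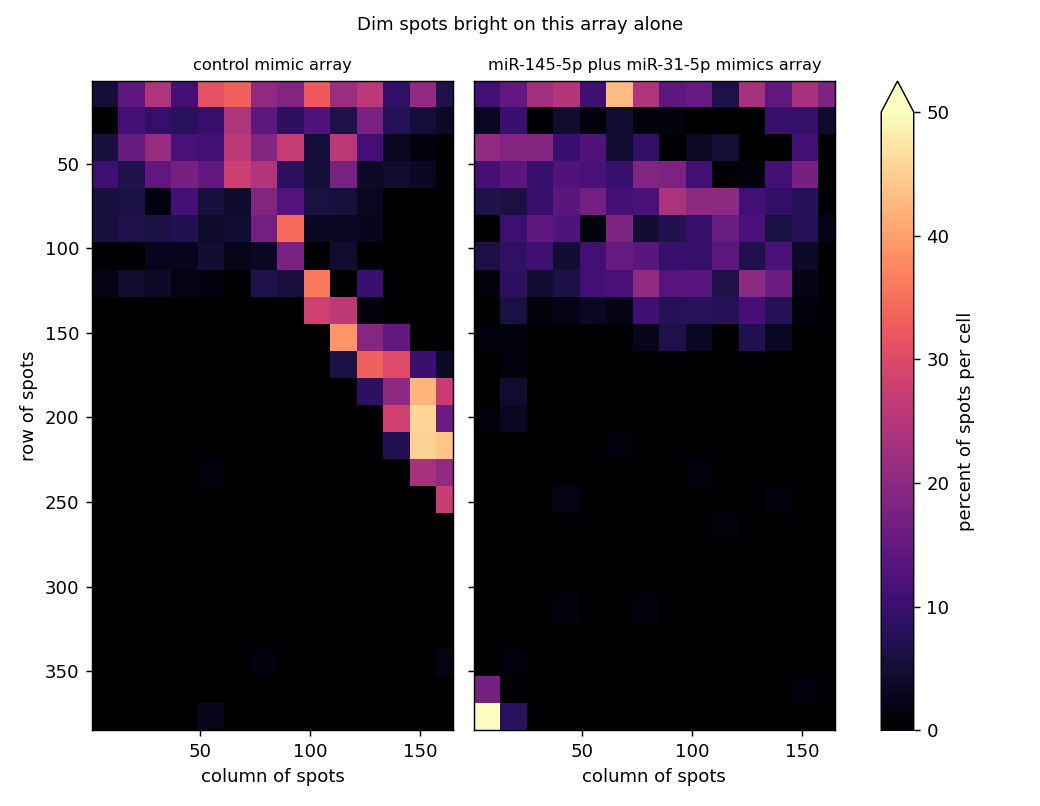
Share of spots with no significant signal on one array that were well above background on the other, in percent, for each cell of 16 rows by 12 columns, plotted by row and column of the array. The highest share on the mimics array was 52.5% at rows 369 to 384 and columns 1 to 12, and the highest on the control array was 45.8% at rows 193 to 208 and columns 145 to 156.

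Among the brighter genes, 51 had every measured probe at least 2-fold lower with the mimics, and 25 of these had all their probes in clean cells. For a gene with 1 measured probe, this asked no more than 2-fold at that probe. Of the 3032 genes with 2 or more measured probes, at any brightness, 14 had all of them at least 2-fold lower and 4 at least 2-fold higher. The 12 of the 51 with the largest difference were named. TMEM109, a transmembrane protein (hg19 chromosome 11, 60690854 to 60690913), was 10.6-fold lower, with a signal of 3931 on the control array and 375 on the mimics array. TMA7, a translation machinery associated protein (chromosome 3, 48485552 to 48485611), was 6.17-fold lower, with differences of -2.76 and -2.49 at its 2 probes. The STK40 probe (chromosome 1, 36805314 to 36805373) read 13079 on the control array and 2439 on the mimics array. MTLN, a small mitochondrial membrane protein, was lower by 3.13-fold, AP1M1, a clathrin adaptor subunit, by 3.10-fold and POLDIP2 by 3.02-fold. The probes of these 6 genes lay in clean cells. MGAT1, the enzyme that opens the synthesis of complex N-glycans, was 3.42-fold lower and WBP11, a splicing factor, 2.99-fold lower, each with 1 of 2 probes in clean cells. For the other four, all probes lay in speckled cells. PCBD1, which recycles the cofactor tetrahydrobiopterin, was 5.74-fold lower, the membrane protein EMP1 3.85-fold, TP53I13 3.40-fold and the lysosomal membrane protein LAPTM4A 3.16-fold. The signals of PCBD1, EMP1, TP53I13 and LAPTM4A differed by 2487, 8810, 3611 and 10665 units, above 937, the 99th percentile of the spots bright on the control array alone. Replicate spots in the brightness range of these 12 genes differed between the arrays with a technical SD of 0.05 to 0.10. Without a filter on dim probes, MTLN had a difference of -0.97.

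Among the brighter genes, 13 had every measured probe at least 2-fold higher, genes with a single probe included, and 12 of them were named. IL1B (chromosome 2, 113587429 to 113587488) read 13337 on the control array and 40690 on the mimics array. CALU, a calcium-binding protein of the secretory pathway, was 2.45-fold higher, the D-type cyclin CCND3 2.35-fold, the microtubule-severing protein KATNAL1 2.13-fold and the kinase MOK 2.09-fold. The probes of these 5 genes lay in clean cells. H3-3A, which encodes the replication-independent histone variant of H3, was 2.08-fold higher at 3 probes, 2 of them in clean cells. The other six genes had their probe in speckled cells. These were C10orf90 at 2.54-fold, ZNF581 at 2.35-fold, the histone gene H3C1 at 2.12-fold, PRELID3B at 2.05-fold, BANF1 at 2.02-fold and the 18S ribosomal RNA RNA18SN5 at 2.77-fold. RNA18SN5 differed by 45093 units, above 1701, the 99th percentile of the spots bright on the mimics array alone, and the other five by less than that. The 28S ribosomal RNA RNA28SN5 had a difference of -0.04. Without a filter on dim probes, C10orf90 had a difference of 0.51. With normexp background correction, MOK, PRELID3B and BANF1 had differences of 0.93, 0.87 and 0.96.

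**Figure D2:**
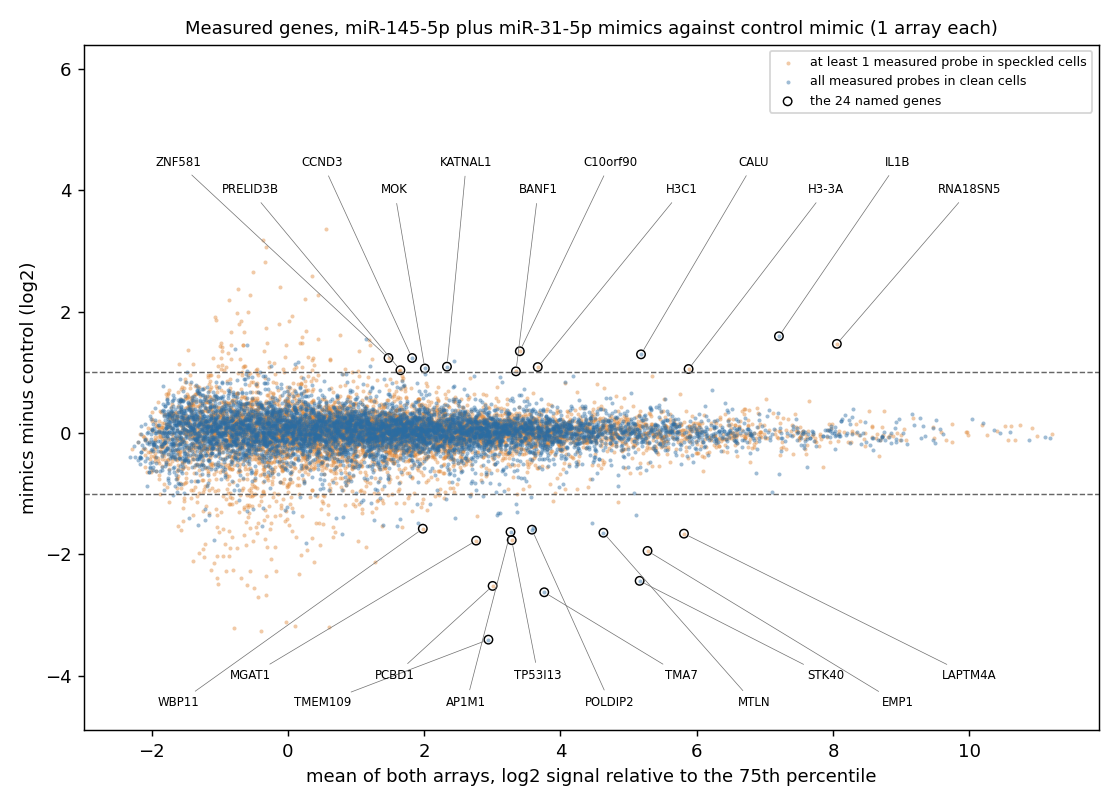
Difference between the arrays (mimics minus control, log2) against the mean of both arrays (log2 signal relative to the 75th percentile) for the 12601 measured genes, 1 array per group. Blue points have all measured probes in clean cells, orange points at least 1 in speckled cells, circles mark the 24 named genes, and dashed lines mark 2-fold, which 103 genes reached upward and 231 downward.

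The reported targets of the 2 microRNAs were lists fixed before the data were examined. Of 40 miR-31-5p targets, 34 were measured, and 25 of these were lower and 9 higher on the mimics array, 5 and 1 of them by at least 2-fold. Their median of -0.29 lay below all 10000 random lists of genes of the same brightness. Besides STK40, the replicative helicase subunit MCM2 was at least 2-fold lower in clean cells, at -1.17. In clean cells, HIF1AN, the asparaginyl hydroxylase of HIF, had a difference of -0.98. Its signals were dim, 77.1 on the control and 39.4 on the mimics array, where the technical SD was 0.36. JAZF1 at -1.62 and the deubiquitinase BAP1 at -1.07 were read in speckled cells. KLF13 had a median of -1.26 over 2 probes, of which the probe in a clean cell gave -0.26. Without a filter on dim probes, the KLF13 difference turned positive. WASF3, an actin regulator, was the only miR-31-5p target at least 2-fold higher, at 1.03, and its probe lay in a speckled cell. With normexp background correction, JAZF1, BAP1, KLF13 and WASF3 had differences of -0.89, -0.95, -0.86 and 0.83. In clean cells the median of 17 targets was -0.26, at percentile 0.01 of the random lists.

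Of 45 miR-145-5p targets, 40 were measured, 27 lower and 13 higher on the mimics array, none of them by 2-fold, and with the arrays scaled by the spike-ins 23 were lower and the median was -0.06. Under the 75th percentile scaling their median of -0.13 lay at percentile 0.03 of the random lists, and in clean cells the median of 24 targets was -0.13 at percentile 0.18. CBFB, the non-DNA-binding partner of the RUNX factors, had the largest difference at -0.80. The epithelial mucin MUC1 had a difference of -0.66, the actin-bundling protein FSCN1 of -0.63, the transcription factors ETS1 of -0.62 and KLF4 of -0.57, and RTKN of -0.45. NRAS, at 0.55, differed the other way. MUC1, FSCN1, ETS1 and NRAS had no probe in a clean cell. The signals of FSCN1 were 13367 and 8728, and those of KLF4 65.8 and 44.9, where the technical SD was 0.36. ETS1 also stands in the miR-31-5p list.

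The DNA replication, mitosis and replication-dependent histone lists had medians below the central 95% of random lists. In the DNA replication list, the median of -0.36 over 19 genes lay below all random lists, in clean cells as well, where it was -0.35 over 14 genes. With the arrays scaled by the spike-ins, 18 of the 19 were lower. MCM2, which is also in the miR-31-5p list, was the only member at least 2-fold lower. The helicase subunits MCM5 and MCM3 had differences of -0.68 and -0.60, and the thymidylate synthase TYMS one of -0.55. Of 20 mitosis genes, 14 were lower and 6 higher, none by 2-fold, with a median of -0.16 at percentile 0.14, or of -0.09 with 13 lower when scaled by the spike-ins. The mitotic kinesin KIF11 had a difference of -0.58, the cyclins CCNB2 and CCNB1 of -0.56 and -0.54, and the kinase TTK of -0.34. All 10 measured replication-dependent histone genes were lower, with a median of -0.27 at percentile 0.11. H4C3 had a difference of -0.58, H1-4 of -0.48, H3C2 of -0.44 and H3C10 of -0.40, whereas H3C1, which was not in the list, was 2.12-fold higher. TYMS, KIF11, CCNB1, TTK, H3C2, H3C10 and H3C1 had no probe in a clean cell.

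Of 19 p53 targets, 12 were lower and 7 higher, with a median of -0.17 at percentile 0.32. It was -0.27 over 11 genes in clean cells and -0.10 when scaled by the spike-ins. SESN2 and the pro-apoptotic BBC3 each had a difference of -0.50, and SPATA18 one of 0.40. AEN, an apoptosis-enhancing nuclease read in a speckled cell, had a difference of 1.54, and of 0.72 where spots with an outlier mark were kept. The microRNA machinery was higher in 11 of 12 genes, with a median of 0.27 at percentile 99.85. Its largest differences were 0.47 for the Argonaute gene AGO4, 0.45 for AGO2, 0.35 for DROSHA and 0.30 for DGCR8. SESN2, SPATA18, AGO4, DROSHA and DGCR8 had no probe in a clean cell, and the AGO2 probe had spots in both kinds. Interferon-stimulated genes had a median of -0.22 at percentile 0.15 over 18 genes. XAF1 at -2.40 and BST2 at -2.15 had their probes in speckled cells, while IFIT3 had a difference of -0.49 and the RNA sensor RIGI, in a speckled cell, of -0.48. In clean cells the median of 11 interferon-stimulated genes was -0.07, at percentile 12.4, inside the central 95% of random lists. The median of interferon-stimulated genes also lay inside it with no filter on dim probes, at percentile 4.27, and at a signal of at least 100 on both arrays, at percentile 2.73. With these lists, 8 of the 29 lay outside the central 95%, and 5% of 29 is 1.45. Some lists share members, and the random lists drew their genes independently of each other, so 1.45 is no expected number for these lists. In clean cells 7 of the 8 also lay outside it, but those cells are part of the same spots and give no independent check.

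**Figure D3:**
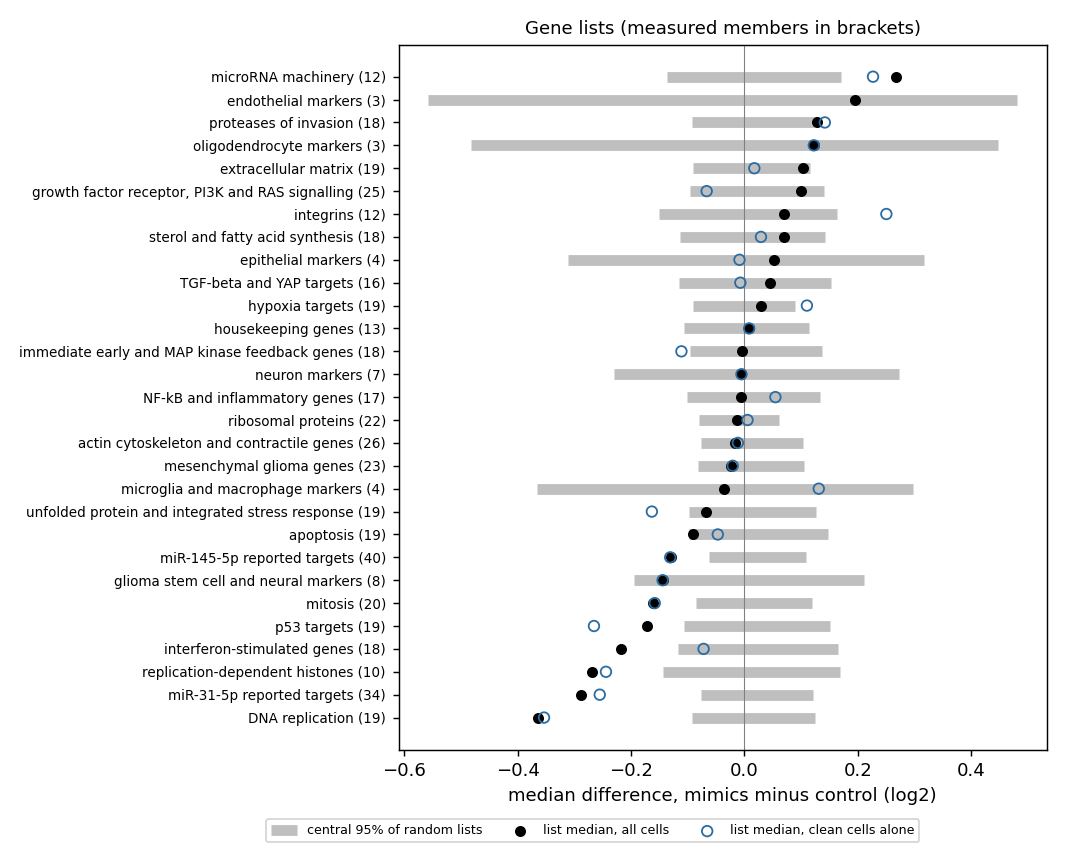
Median difference (mimics minus control, log2) of the 29 gene lists, with measured members in brackets. Black points are all cells, open circles clean cells alone, and grey bars the central 95% of 10000 random lists of the same brightness; DNA replication lay lowest at -0.36 and microRNA machinery highest at 0.27.

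The other 21 lists lay inside the central 95% over all cells. In clean cells alone, integrins, hypoxia targets, the unfolded protein and integrated stress response, and immediate early and MAP kinase feedback genes lay outside it. Scaling by the spike-ins raised every difference by 0.07 and left the percentiles as they were, so that medians between -0.07 and 0 turned sign. For lists of invasion and adhesion, proteases of invasion had a median of 0.13 at percentile 97.25, extracellular matrix genes of 0.10, integrins of 0.07, and actin cytoskeleton and contractile genes of -0.02. In clean cells the extracellular matrix median was 0.02 and that of integrins 0.25, and scaled by the spike-ins the actin median was 0.05. The matrix metalloproteinase MMP3 was 2.85-fold lower in clean cells, MMP1 had a difference of 0.50, the protease inhibitor TIMP3 of -0.53, and LUM of -0.69. The integrin genes ITGB1 and ITGB3 had differences of 0.42 and 0.39, and the actin-associated TAGLN and TLN1 of 0.56 and 0.44. Glioma stem cell and neural markers had a median of -0.14 over 8 measured genes, with ID1 at -0.68 and MSI1 at -0.48. Mesenchymal glioma genes had a median of -0.02, with the receptor MET at 0.74 and S100A4 at -0.53. TIMP3, TAGLN and MET had no probe in a clean cell.

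In lists of signalling and stress, the median was -0.01 for NF-kB and inflammatory genes, where PTGS2 had a difference of 0.94, IL1A of 0.55 and CXCL1 of -0.36. Growth factor receptor, PI3K and RAS signalling genes had a median of 0.10, with FGFR1 at -0.68, but in clean cells the median of 14 of them was -0.07 at percentile 9.40. TGF-beta and YAP targets had a median of 0.04, and their member TGFB2 was at -2.08 in a speckled cell. The median was 0.00 for immediate early and MAP kinase feedback genes, with FOS at -0.96 and DUSP6 at 0.66. Apoptosis genes had a median of -0.09, where XIAP at -0.47 and CASP8 at -0.40 had differences of 0.18 and 0.15 at their probe in clean cells, and CASP9 at -0.36 and BAX at -0.35 had all their probes there. Hypoxia targets had a median of 0.03, with EGLN3 at -0.97, KDM3A at 0.75 and the glucose transporter SLC2A1 at -0.66. EGLN3 read 71.2 on the control and 36.8 on the mimics array, where the technical SD was 0.36. Genes of the unfolded protein and integrated stress response had a median of -0.07, with SEL1L at 0.73, VLDLR at 0.64 and PSAT1 at -0.62. Sterol and fatty acid synthesis had a median of 0.07, with INSIG1 at 0.72 and IDI1 at -0.47. Ribosomal proteins and housekeeping genes had medians of -0.01 and 0.01, with RPL14 at 0.20, RPS9 at -0.17, TBP at 0.20 and B2M at -0.20. The RPS9 probe in a clean cell gave -0.11. In clean cells the median was 0.05 for NF-kB and inflammatory genes, -0.01 for TGF-beta and YAP targets and 0.01 for ribosomal proteins, each of the other sign than over all cells. In clean cells the medians also were -0.05 for apoptosis genes, 0.11 for hypoxia targets, -0.16 for the stress response, 0.03 for sterol and fatty acid synthesis and -0.11 for immediate early genes. IL1A, FGFR1, FOS, KDM3A, SLC2A1, IDI1 and TBP had no probe in a clean cell.

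Markers of other cell types were sparsely measured. Of 12 neuron markers 7 were measured, with a median of -0.01, MAP2 at -0.78 and SYT1 at 0.57. The MAP2 probe in a clean cell gave -0.27. The medians were 0.12 for 3 oligodendrocyte markers, -0.04 for 4 microglia and macrophage markers, 0.19 for 3 endothelial markers and 0.05 for 4 epithelial markers. The largest differences in these lists were 0.17 for CNP, 0.76 for TYROBP, 0.65 for PECAM1 and 0.12 for KRT8. The CNP probe in a clean cell gave 0.29, and TYROBP, PECAM1 and KRT8 had no probe in one. At the dim signals of TYROBP and PECAM1 the technical SD was 0.36. In clean cells, 3 epithelial markers had a median of -0.01 and the 1 microglia and macrophage marker measured there, FCER1G, a difference of 0.13.

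Some genes were above background on 1 array alone. At least 2-fold bounds were reached by 193 genes with the mimics and by 398 in the control, but only 7 and 6 of these had a probe in a clean cell. The cells were themselves defined by spots of this kind, so this split is not independent of the counts. The 4 largest bounds with the mimics were at least 33.3-fold for LOC101928438, 32.8-fold for NKAIN3, 24.7-fold for CES3 and 23.3-fold for LINC03022. In the control they were at least 25.8-fold for ISL1, 24.8-fold for TLX1NB, 20.5-fold for ARHGAP15 and 18.1-fold for EFNB3. Each of these 8 genes had 1 probe, in a speckled cell.

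Of the transcripts that host the 2 microRNAs, MIR31HG had 3 probes, of which 0 were above background on the control array and 1 on the mimics array. That MIR31HG probe read 28.3 on the control array and 29.6 on the mimics array, a difference of 0.05. CARMN, the present name of MIR143HG, had 7 probes, with 2 above background on the control array and 3 on the mimics array. The CARMN probe above background on the mimics array alone read 33.1 there and lay in a speckled cell. Of the 2 above background on both arrays, the probe in a clean cell had a difference of 0.96 and the other, in a speckled cell, of -0.62. The array had no probes for MIR145 or MIR31. Mimics are not transcribed, so host transcripts do not measure their uptake.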

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

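The division of the array into clean and speckled cells and the test of a response in this part were chosen after the result was seen. Transcripts that the gene table does not name stood outside the comparison of named genes. Of 3316 such transcripts measured, 52 were at least 2-fold higher and 109 at least 2-fold lower with the mimics. In clean cells, 3 of 1824 were at least 2-fold higher and 3 at least 2-fold lower, 0.164% each way. Among simulated named genes without a difference, over the whole array and thus not the same set, 0.354% reached 2-fold. The noise simulated for signals of 16 to 64 was also wider than measured, so this share is no technical level for the unnamed transcripts. Of the 3 higher transcripts, 2 are named, after their values were seen, LOC729770 at 1.24 and lnc-AKAP14-1 at 1.22. The lower ones had differences of -1.54, -1.18 and -1.04, the first of them the largest of all 6, and each of the 6 had 1 probe. With 1 array per group, none of these was set against a spread between cultures.

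Genes at least 2-fold away were more frequent in speckled cells, in both directions. A response of the U87 cells that all probes of a gene would read is argued against as the whole cause of the higher calls. For 21 genes called higher by probes in speckled cells, the upper quartile at their other probes in clean cells was 0.221. The median there was 0.127, and for 60 genes called lower it was -0.0424, as bright specks on one array could leave them. At the clean probe too, 2 of the 21 and 11 of the 60 were at least 2-fold away in the same direction. Among genes with probes in both kinds of cell, 3 were called higher and 17 lower by a clean probe. The same 2 and 11 genes were those of them also called at the other probe, so they are no further evidence. Part of the calls in both directions therefore stays open to a response, and genes with a single probe in a speckled cell could not be checked in this way. Probe positions do not tell whether both probes of a gene read the same transcripts, so a response read by a single probe stays possible.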

How the results depend on the processing

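No paired analysis was possible because each group holds 1 array. Clean cells, scaling by the spike-ins and the use of spot marks alone were chosen after seeing the data. The genes at least 2-fold higher with the mimics numbered 103, and 38 with normexp, 753 with no filter on dim probes, 40 at a signal of at least 100, 17 in clean cells alone, 13 in clean cells scaled on their own spots, 424 at 1.5-fold and 27 at 3-fold. The genes at least 2-fold lower with the mimics numbered 231, and 103, 1077, 109, 67, 88, 643 and 70 under the same settings. The normexp offset shrinks differences of dim genes, the filters and thresholds admit more or fewer genes, and clean cells also hold fewer genes, with a lower share of them at 2-fold. The genes only above background with the mimics numbered 193 (105 with the floor at the 5th percentile, 8 in clean cells and 6 in clean cells scaled on their own spots) and the genes only above background in the control 398 (252, 7 and 8). Of the 24 largest named genes, 14 were measured in clean cells, where all 14 kept 2-fold, or 12 scaled on their own spots, without H3-3A and MOK. KLF13 reversed to 0.082 with no filter, where dim probes joined its median. Both target lists stayed below the central 95% under every setting run, at -0.06 to -0.22 for miR-145-5p and -0.19 to -0.34 for miR-31-5p. Of 29 lists, 7 to 11 lay outside it, and over all other lists and settings 14 medians came to lie outside it and 4 inside. Among single named genes 1351 values kept their side or stayed within the technical spread, 123 moved beyond it, 17 lost 2-fold and 4 gained it. Having no filter shifted the median of all genes by -0.12, and other settings by -0.08 to 0.07. Scaling by the spike-ins gave 133 higher and 197 lower genes. A signal of at least 100 on both arrays was reached by 10355 genes, and dimmer spots had the widest technical spread. Seed sites in 3′ untranslated regions, with their alternatives, were not run for want of sequence.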

Other observations

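All tests in this part were chosen after the result was seen, except the base composition test and the comparison of 7-base with 6-base matches. Genes whose probes held a miR-31-5p seed match were lower with the mimics. The 121 such genes had a median of -0.09, below all 10000 random lists, and 9 of them (7.44%) were at least 2-fold lower, against 1.83% of all genes. The 9 were TP53I13, the iron-sulfur cluster assembly gene ISCA2 at -1.56, MMP3 at -1.51, the mitochondrial thiolase ACAA2 at -1.49, SLC8B1 at -1.25, MCM2 at -1.17, the mitochondrial ribosomal gene MRPL34 at -1.13, AKAP7 at -1.06 and the kinetochore gene SPC25 at -1.01. Probes of ISCA2, MMP3, ACAA2 and MCM2 lay in clean cells. The 216 genes with a miR-145-5p seed match had a median of 0.00 at percentile 15.1, and MUC3A at -1.26 and TAF1B at -1.10 were the 2 at least 2-fold lower.

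Of 12155 words of 7 bases, the miR-31-5p word CTTGCCA ranked 21 from the lowest by median and 1 by standardised mean, and TCTTGCC ranked 87 and 7. The miR-145-5p words AACTGGA and ACTGGAA ranked 3794 and 2665 by median, and 3894 and 3055 by standardised mean. In clean cells, among 9846 words, CTTGCCA ranked 83 and 12, and TCTTGCC 4 and 1.

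The lower values of genes with a miR-31-5p seed match were weighed as a pattern. Specks are argued against, because in clean cells the median of 65 such genes was -0.08, at percentile 0.03 of random lists. Base composition is argued against too, because even the seed word farther from the lowest rank lay within the lowest 2.61% of the words made of the same bases. Repression through the seed may be the cause, but the comparison with shorter matches does not settle it. Genes with a 7-base match differed from genes with the 6-base match alone by -0.0530, with a bootstrap range of -0.15 to 0.01 that includes 0. In clean cells that difference was -0.02, with a range of -0.13 to 0.07. The 103 genes with the 6-base match alone were themselves low, with a median of -0.04 at percentile 1.22. With 1 array per group and probes in place of 3′ untranslated regions, repression through the seed stays a hypothesis.

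In clean cells more genes were lower than higher with the mimics, 67 against 17. Weaker detection of dim spots on the mimics array is argued against, since the ratio of lower to higher genes was 4.86 among brighter genes. Scaling stays open as a cause, since the ratio was 2.11 with the arrays scaled to the median of the 7 spike-ins and 0.926 to 3.72 with single spike-ins. The 0.926 came from the spike-in with the widest SD over its spots, 0.23, and the others gave 1.62 to 3.72. The 5 scalings tried before gave ratios of 3.30 to 3.94 but hardly differed from each other, so they decide nothing, and clean cells scaled on their own spots gave 88 lower against 13 higher. A response to the mimics could be the cause too, but with 1 array per group it cannot be told apart from a difference between the 2 cultures.

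In clean cells alone, 4 lists lay outside the central 95% that lay inside it over all cells. Integrins had a median of 0.25 at percentile 99.09, hypoxia targets of 0.11 at 98.59, unfolded protein and integrated stress response genes of -0.16 at 0.79, and immediate early and MAP kinase feedback genes of -0.11 at 2.49.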
